A study of Oryctolagus cuniculus with 8 samples.

How the data were processed

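The series holds 8 RNA-seq libraries of rabbit limbal epithelial cells sorted by Hoechst dye into SP (4 samples) and NSP cells (4 samples) and sequenced on an Ion Proton instrument, per the labels. The aligner, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of fixed-width text with 163 fields of 8 characters in 6 stacked blocks of lines and 20922 gene entries. Neighbouring values touch, so the table was read by character position. The headers of the per-library fields are truncated at 8 characters and show the group, but not the measure. The field used for each library holds whole numbers for every gene and was taken as the unscaled count of exon reads. The deposited group means were recomputed from these values, with a largest difference of 0.05, and the deposited fold changes, p-values and corrected p-values come from an EDGE test, per the file headers. The other 142 per-library fields, among them any RPKM values, were not used here. The columns name the group but no sample, so libraries are numbered 1 to 4 in column order, and which GEO sample, animal or day each number stands for is not known here.

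Gene names are truncated at 8 characters as well. Names under 8 characters are complete (10603 genes), and 313 names of 8 characters matched exactly 1 symbol in a RefSeq gene table (assembly mOryCun1.1, used for names only). The remaining 10006 entries, among them 8886 LOC entries and 309 numbered gene copies, had no usable name and held 10.1% of reads. They stayed in library totals and tests, and no such gene is named. ABCG2, KRT14, KRT5, MKI67, CCND1 and NOTCH1 had no usable entry. No coordinates are given.

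Counts were scaled with TMM factors (trims of 30% and 5%) computed here, and genes were kept with a CPM of at least 0.508 (10 reads in the median library) in 4 or more libraries and at least 15 reads in all, which left 10012 genes. Each gene was tested with limma-voom (limma 3.58.1 in R 4.3.3; count offset 0.5; model of group only) with empirical Bayes moderation, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The plan written before the data were examined named a quasi-likelihood count test of edgeR, which was not used, nor was DESeq2, although the recovered values are counts that such a test can take. The fields touch, so a reading of the table by columns shows no count column, and limma-voom was chosen instead. The counts were read by character position all the same, so this did not keep the planned test from being run. The plan named limma-voom for neither counts nor normalized values. Parsing and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

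There were 33 gene lists fixed before the data were examined. For each, members past the threshold were counted over all tested genes and over the list alone, and the list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all adjusted over the lists. The lists cover ABC transporters, limbal, corneal and conjunctival epithelium, mitosis, replication, quiescence, immediate early and heat shock genes, stromal, melanocyte, T and NK, myeloid, pan-leukocyte, endothelial and Schwann cell markers, MHC class I and II, interferon, NF-kB, Wnt, Notch and TGF-beta genes, epithelial-mesenchymal transition, junctions, basement membrane, glycolysis, oxidative phosphorylation, ribosomal proteins, hypoxia, antioxidant defence, cholesterol synthesis and stem cell factors. Genes named in the text follow a rule fixed at the same time: 25 fixed genes, the 10 largest rises and 10 largest falls among named genes past the threshold whose groups do not overlap, and up to 3 members per list and direction with the smallest p. Some genes that the rule names are not reported here; they stayed in all tests and list counts. Where a group had no read, fold changes are bounds against 3 reads over the group, and with 1 to 3 reads they carry an exact 95% counting interval. Library totals, detected genes and scores were compared by exact permutation over all 70 splits, whose smallest two-sided p is 0.029.

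The procedure was tested on simulated counts made from these libraries (9868 genes in the simulation). For SP versus NSP it called 7 of 96 genes changed 2-fold, 66 of 97 genes changed 8-fold and 4 of 9675 unchanged genes, so at this depth and spread most simulated 2-fold changes stayed uncalled. The simulation changed 200 genes, a smaller share than the 30.7% called in the real comparison, which made its adjusted threshold stricter. Alternatives were median-ratio and upper-quartile factors, no filter beyond 1 read, a filter of 10 reads in 4 libraries, and each library left out in turn. After the data were seen, limma-trend on log2 CPM with 0.5 added, voom with quality weights and thinning of all libraries to 15553295 reads were added. Values far from the rest of a group of 4 were found with Dixon's ratio (critical value 0.829) on CPM in groups with more than 3 reads.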

Results

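The side population (SP) of a tissue is the small fraction of cells that pumps out the DNA dye Hoechst and so stays dim in flow cytometry, a property used to look for stem cells. Here, SP and non-side-population (NSP) cells were sorted from the epithelium of the limbus, the rim between cornea and conjunctiva, of New Zealand white rabbits, an albino breed. Total RNA of 4 SP and 4 NSP samples was sequenced on an Ion Proton instrument. The count table held between 15553295 and 18931836 exon reads per SP library and between 20445565 and 23529101 per NSP library. The comparison asks which genes differ in expression between the dye-excluding cells and the remaining limbal cells. Levels below are CPM, the reads scaled to a common total, as mean ± SD over 4 libraries per group, and log2 fold changes are SP over NSP with their standard errors from limma-voom. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

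The drug efflux pump gene ABCB1, which encodes P-glycoprotein, stood at 1283 ± 549.8 CPM in SP and 8.76 ± 1.8 CPM in NSP cells, a log2 fold change of 7.12 ± 0.39 (limma-voom adjusted p = 1.46e-05). Marker lists of T and NK and of endothelial cells also rose in these SP libraries (median log2 fold changes 9.96 and 8.70). Which cells held the ABCB1 RNA was not tested. ABCC4, an exporter of organic anions and cyclic nucleotides, was also higher in SP, with a log2 fold change of 1.69 ± 0.39. The cholesterol exporter ABCA1 was lower, at -1.48 ± 0.24. ABCC1, another multidrug exporter, did not pass the threshold, with 67.7 ± 13.4 CPM in SP and 83.4 ± 32.4 CPM in NSP (adjusted p = 0.696). Of 14 measured members of the list of ABC transporters, 2 rose and 1 fell, the same numbers as when adjusted over the list alone, while 2 rose and 2 fell with median-ratio factors and 2 rose and 3 fell with upper-quartile factors. The list had a median log2 fold change of -0.21 but a mean of 0.51; camera, which leaned down, did not call it (adjusted p = 0.715), while fry called it up (adjusted p = 0.0322). ABCG2, the pump most often tied to the side population, was not analysed here.

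KRT15, TP63 and PAX6, genes of the limbal epithelium, were lower in SP cells. Keratin 15 (KRT15), a marker of basal limbal cells, was at 577 ± 975 CPM in SP and 15218 ± 2734 CPM in NSP (log2 fold change -6.41 ± 1.02, limma-voom adjusted p = 0.00131). TP63, the master regulator of stratified epithelia and a limbal stem cell marker, fell from 276 ± 84.1 to 13.3 ± 13.3 CPM, a log2 fold change of -5.42 ± 0.75 (adjusted p = 0.000654). PAX6, the transcription factor of eye development and corneal identity, had a log2 fold change of -3.30 ± 0.64 (adjusted p = 0.00351). Of 21 measured members of the list of limbal stem and progenitor genes, 10 fell and 3 rose, or 13 and 3 when adjusted over the list alone. The falls with the smallest p included the glycolytic enzyme ENO1 (-3.04) and the chemokine CXCL14 (-6.79). The members that rose were KIT (2.62), a receptor also used by melanocytes and mast cells, the redox regulator TXNIP (2.38) and the polycomb gene BMI1 (2.02). BMI1 lost its call in 6 of the 8 fits that leave out 1 library, those without SP replicate 1 or 3 or any NSP replicate, with adjusted p up to 0.102. The limbal list was lower in SP by camera (adjusted p = 0.00132), with adjusted p = 0.154 with an estimated correlation. Of the 21 measured genes of this list, 10 also stand in another list. KRT14, KRT5, MKI67, CCND1 and NOTCH1 were not analysed here.

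Most measured genes of corneal differentiation fell as well. The cornea-specific keratin pair KRT3 and KRT12 had log2 fold changes of -3.41 ± 0.87 and -3.30 ± 0.87 (limma-voom adjusted p = 0.0137 and 0.0163). KRT12 was at 1236 ± 1743 CPM in SP and 7025 ± 4938 CPM in NSP, and its values overlapped between the groups because SP replicate 1 held 3833 CPM while the other SP libraries held 169.1 to 645 CPM. Of 27 measured members of the corneal list, 19 fell and 0 rose, with 21 falls when adjusted over the list alone, and the median log2 fold change was -2.49. The smallest p-values belonged to transketolase (TKT, -3.05), an abundant corneal enzyme, the matrix protein gene TGFBI (-3.78), mutated in corneal dystrophies, and the gap junction gene GJB2 (-3.83). The gap junction gene GJA1 did not pass, with a log2 fold change of -0.40 ± 0.52. Camera placed the list below other genes (adjusted p = 1.57e-08), which was lost with an estimated correlation (adjusted p = 0.336). In the list of conjunctival and goblet genes, 2 of 10 measured members fell and 1 rose, the same as when adjusted over the list alone. These were the mucosal keratins KRT13 (-2.85 ± 0.65) and KRT4 (-1.47 ± 0.48), which fell, and the simple-epithelial keratin KRT18 (1.38 ± 0.43), which rose. The conjunctival list was not called (camera adjusted p = 0.38). KRT4 and KRT18 lost their calls without several single libraries, with adjusted p up to 0.105 for KRT4 (without SP replicate 1 or any NSP replicate) and 0.125 for KRT18 (without any library except SP replicate 3), KRT4 moved to -0.96 without SP replicate 3, and KRT18 also lost its call with upper-quartile factors (adjusted p = 0.0569).

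**Figure D1:**
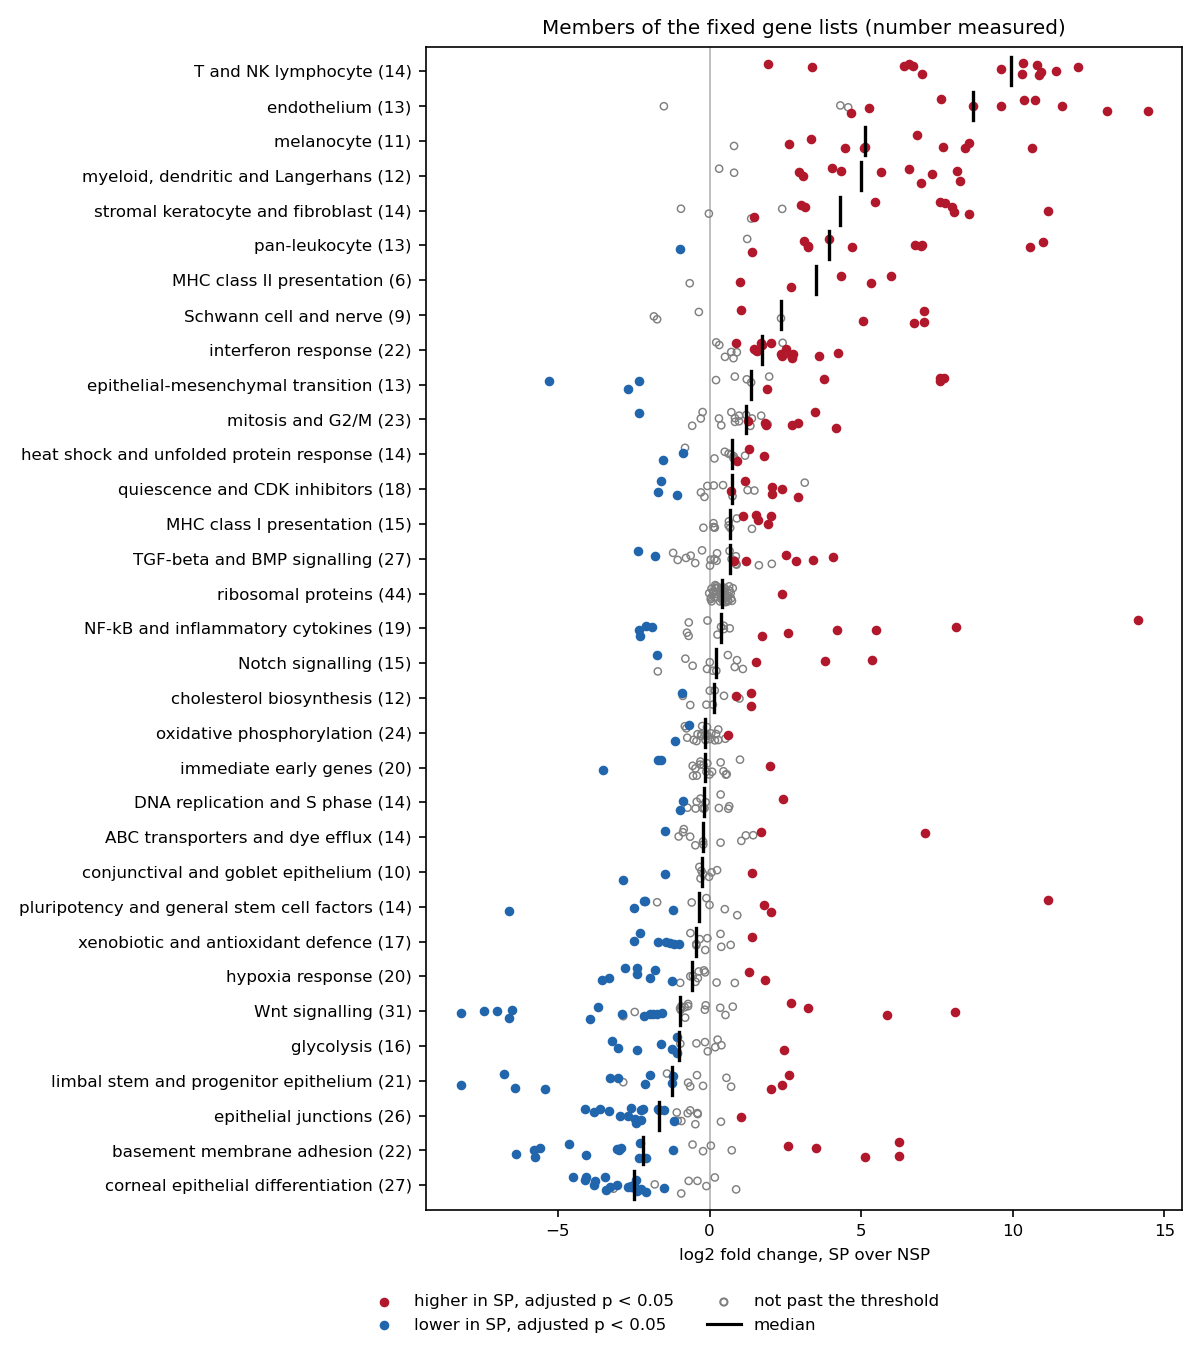
Log2 fold change (SP over NSP, horizontal axis) of each measured member of the 33 fixed gene lists, with the number measured in parentheses. Filled points passed the threshold, open points did not, and black bars mark list medians, which run from -2.49 for corneal differentiation to 9.96 for T and NK lymphocyte genes.

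Most measured marker genes of other cell types of the limbus were higher in SP cells. A marker nearly absent from NSP could pass the filter only with enough reads in all SP libraries, which favours rises among the measured markers. Not measured were 10 of 24 listed T and NK, 12 of 24 myeloid and 10 of 24 stromal genes. The same held for 7 of 20 endothelial, 7 of 20 pan-leukocyte, 3 of 14 melanocyte and 6 of 15 Schwann cell genes. Some of these may instead lack a usable name. The endothelial adhesion gene PECAM1 was at 688 ± 399 CPM in SP against 7 reads in all NSP libraries together (log2 fold change 13.10 ± 1.72, limma-voom adjusted p = 0.000477). The leukocyte gene PTPRC, which encodes CD45, had a log2 fold change of 10.57 ± 1.75, and the type I collagen gene COL1A2 one of 3.14 ± 0.40 (adjusted p = 0.00161 and 0.000423). MITF, the master regulator of melanocytes, was at 51.8 ± 36.4 CPM in SP and 5.22 ± 3.01 CPM in NSP (3.34 ± 0.86, adjusted p = 0.0142). All 14 measured T and NK lymphocyte genes rose, among them TBX21 (6.42), CD247 (10.94) and CD8B, which had no NSP read and was at least 963-fold higher. Of 13 endothelial genes 10 rose, including EMCN (8.70) and TEK. TEK had 2 reads in NSP, for a ratio of 5270 with an exact 95% counting interval from 1458 to 43520. Of 11 melanocyte genes 10 rose, including the pigment cell genes PMEL (5.13) and TYRP1 (4.47), and of 14 stromal genes 10 rose, including COL1A1 (8.07) and COL3A1, which was at least 319-fold higher against no NSP read. Among 12 myeloid and Langerhans genes 10 rose, including LAPTM5 (6.99), CD83 (5.65) and SPI1 (8.17, or 5.16 with limma-trend). Of 13 pan-leukocyte genes 11 rose, including CORO1A (3.92) and WAS (3.25), and ARHGDIB fell (-0.98). Of 9 Schwann cell and nerve genes 5 rose and none fell, the rises including PMP22 (7.06) and NCAM1 (5.07).

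Adjusted over the list alone, the numbers that rose were 14 T and NK, 11 endothelial, 10 melanocyte, 12 stromal, 11 myeloid, 12 pan-leukocyte and 5 Schwann cell genes, while 1 stromal and 1 pan-leukocyte gene fell. The median log2 fold changes were 9.96 for T and NK, 8.70 for endothelial, 5.13 for melanocyte, 4.99 for myeloid, 4.31 for stromal, 3.92 for pan-leukocyte and 2.36 for Schwann cell genes. With genes that had no NSP read set to their bound, the T and NK median was 9.73 and the stromal one 4.31. Camera called 6 of these 7 lists higher in SP, with adjusted p = 5.37e-08 for T and NK, 3.47e-07 for pan-leukocyte, 4.97e-06 for myeloid, 1.54e-05 for melanocyte, 1.93e-05 for endothelial and 0.000163 for stromal genes. It did not call the Schwann cell list (adjusted p = 0.0648), but called it with median-ratio factors (0.0460), upper-quartile factors (0.0383), no filter (0.0289), limma-trend (0.0389) and without SP replicate 3 (0.0367). With an estimated correlation these 6 calls were lost, at adjusted p = 0.336 for T and NK, 0.336 for pan-leukocyte, 0.154 for myeloid, 0.34 for melanocyte, 0.37 for endothelial and 0.336 for stromal genes. None of the 19 list calls of this report held with an estimated correlation, where the lowest adjusted p was 0.154. The estimate was 0.83 for the endothelial list but only 0.0005 for the limbal list, under the preset 0.01. A higher correlation between genes therefore cannot be why the limbal list lost its call. Fry, which tests whether a list's genes move one way, called all 7 (adjusted p from 0.00046 to 0.0103). Unlike camera, it does not compare a list with other genes, so its calls do not show that these lists moved more than others.

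The 10 named genes with the largest rises, of which VWF and PECAM1 stand in a cell type list and CCL5 in the cytokine list, were VWF (14.45), SELP (14.14), ACKR1, AQP1 (13.11) and PECAM1, which endothelial cells express, the chemokine CCL5 (14.15) and the chemokine receptor CXCR6, which T cells express, the B-lineage gene MZB1, and the lymphoid adaptor genes SAMSN1 and SASH3. CXCR6, MZB1 and SAMSN1 had no read in any NSP library and were at least 11810-fold, 9076-fold and 3859-fold higher in SP, taking 3 reads over the NSP group as the floor. ACKR1 and SASH3 had 3 NSP reads each, for ratios of 14920 (95% counting interval 5104 to 72340) and 6147 (2103 to 29810). VWF reached 3239 ± 3006 CPM in SP, and its spread between SP libraries was nearly as large as its mean. Among the 10 largest falls were EXTL1 (-9.86), GPHB5 (-9.60), TENM2 (-9.36), FRZB (-8.21), ART4 (-8.14), CDH10 (-7.99), FRAS1 (-7.80), DLX3 (-7.73, or -4.58 with limma-trend) and TSPYL5. FRZB is a secreted Wnt antagonist, FRAS1 a protein of epithelial basement membranes and DLX3 a homeobox factor of ectodermal epithelia. TSPYL5 had no SP read and 6.39 ± 2.35 CPM in NSP, and was at least 149-fold lower. The rule for these genes asks that the libraries of the groups do not overlap, which held for 3285 or 32.8% of all tested genes, against 2.86% by chance. Floors and intervals cover counting error only, since the reads carry no molecular tags in the sources used here.

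**Figure D2:**
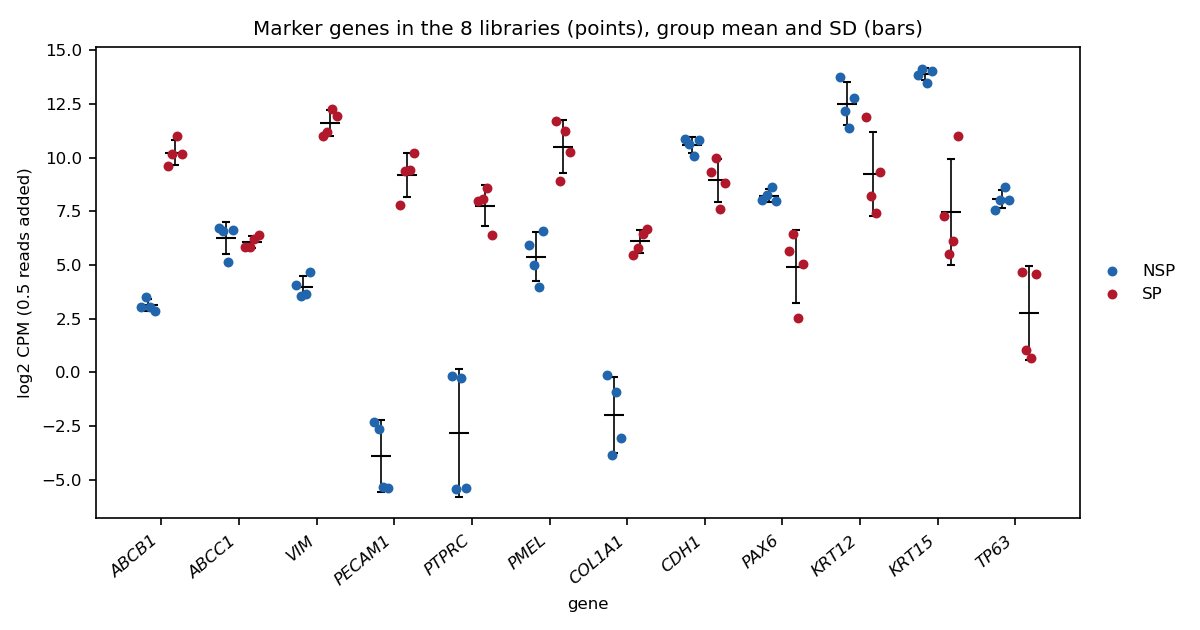
Log2 CPM with 0.5 reads added (vertical axis) of 12 genes in the 4 NSP (blue) and 4 SP (red) libraries, where points are libraries and bars the group mean and SD. ABCB1, VIM, PECAM1, PTPRC, PMEL and COL1A1 lie higher in all SP libraries, CDH1, PAX6, KRT15 and TP63 lower in all SP libraries, and the groups overlap for KRT12 and ABCC1.

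The intermediate filament gene VIM, typical of mesenchymal, endothelial and immune cells, rose from 16.7 ± 6.3 CPM in NSP to 3314 ± 1371 CPM in SP (log2 fold change 7.61 ± 0.38, limma-voom adjusted p = 1.18e-05), and CDH1, the epithelial cadherin, had a log2 fold change of -1.66 ± 0.45 (adjusted p = 0.0185). Of 26 epithelial junction genes 16 fell and 1 rose, the same as when adjusted over the list alone. The falls were led by GJB2, the desmosomal cadherin DSG3 (-4.11) and the tight junction gene CLDN1 (-3.31), and TJP1 rose (1.02). Of 22 basement membrane and adhesion genes 13 fell and 5 rose, also the same over the list alone. The hemidesmosome-anchoring laminin gene LAMB3 (-5.78) and the integrins ITGB5 (-2.92) and ITGA2 (-2.30) fell. COL4A2 (6.26), COL4A1 (6.25) and the perlecan gene HSPG2 (3.52), which encode vessel basement membrane proteins among others, rose, as the endothelial markers did. Of 13 genes of epithelial-mesenchymal transition 5 rose and 3 fell, or 8 and 3 over the list alone. TCF4 (3.76) and ZEB1 (7.72) rose, while SNAI2 (-2.70 ± 0.37, adjusted p = 0.000594), ITGAV (-2.34) and MMP3 (-5.29, or -2.92 with limma-trend) fell. Camera called the junction list (adjusted p = 3.47e-07) and the basement membrane list (adjusted p = 0.000602) lower in SP, with adjusted p = 0.34 and 0.34 with an estimated correlation, and did not call the transition list (adjusted p = 0.0893). The transition list was called higher with upper-quartile factors (adjusted p = 0.0461), without SP replicate 1 (0.0388) and by fry (0.0103). The calls of CDH1 (without NSP replicate 4, adjusted p = 0.0519), of MMP3 (without SP replicate 1, 2 or 3 or NSP replicate 4, up to 0.0771) and of TJP1 (without any library except SP replicate 2, up to 0.127) ended without single libraries, and that of TJP1 also under both other scalings, without the filter (0.0620) and with quality weights (0.62, adjusted p = 0.152).

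Several antigen presentation and interferon-stimulated genes rose in SP cells, as the leukocyte markers did. CD74, the invariant chain of MHC class II, was at 4827 ± 1812 CPM in SP and 263 ± 167 CPM in NSP (log2 fold change 4.33 ± 0.46, limma-voom adjusted p = 0.000215). Of 6 measured class II genes 5 rose and none fell, among them RLA-DR-ALPHA (5.98) and the lysosomal protease gene CTSS (2.68). Of 15 class I genes 5 rose and none fell, including the immunoproteasome subunit PSMB8 (2.02), the peptide transporter TAP1 (1.58) and NLRC5 (1.93), the last of which lost its call without NSP replicate 1 (adjusted p = 0.0542). Of 22 interferon response genes 14 rose and none fell, including IFIT3 (4.25), IFIT2 (3.62) and HERC6 (2.73). Over the lists alone the rises numbered 5, 5 and 17. Camera called class II (adjusted p = 0.00435), class I (adjusted p = 0.02) and interferon response (adjusted p = 1.08e-05) higher in SP, with adjusted p = 0.336, 0.37 and 0.34 with an estimated correlation. The class I call ended without SP replicate 4 (adjusted p = 0.0694). The inflammatory cytokine list moved both ways, with 6 of 19 genes higher and 4 lower (7 and 4 over the list alone; camera adjusted p = 0.548, fry up with adjusted p = 0.0381). CCL5, TNF (2.58) and IL6 (4.21) rose, and the interleukin-1 antagonist gene IL1RN (-2.10), CXCL8 (-2.29) and IL1A (-2.34) fell, IL1A losing its call without SP replicate 2 (adjusted p = 0.0504).

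More Wnt pathway genes fell than rose in SP cells, in libraries where the corneal list had a median log2 fold change of -2.49. Of 31 measured members 13 fell, 4 rose and 14 did not pass, or 15 and 4 over the list alone. The ubiquitin ligase gene RNF43 (-2.89), the ligand gene WNT6 (-7.00, or -3.96 with limma-trend) and FRZB fell, while the Wnt inhibitor gene APCDD1 (5.85) and the transcription factor genes LEF1 (8.10) and TCF7 (2.70), which lymphocytes also express, rose. Camera called the list lower (limma-voom values, adjusted p = 0.00101), and the call was lost at adjusted p = 0.361 with an estimated correlation. Among 15 Notch genes 3 rose and 1 fell, also over the list alone. The rises were RBPJ (1.53), the endothelial tip cell ligand DLL4 (5.35) and HEYL (3.81), and the ligand JAG1 fell (-1.74). Among 27 TGF-beta and BMP genes 6 rose and 2 fell (9 and 2 over the list alone). The inhibitor genes SMAD7 (4.08), SKIL (1.19) and BAMBI (3.41) rose, and the ligand genes INHBA (-2.37) and BMP4 (-1.79) fell. Among 14 general stem cell factors 5 fell and 3 rose (5 and 4 over the list alone), and 10 of the 14 also stand in another list. The falls included the intestinal stem cell receptor LGR5 (-6.61), NGFR (-2.12) and the basal integrin ITGA6 (-1.22), and the rises CD34 (11.17), which vessels also express, NT5E (1.78) and BMI1. Camera called none of the Notch, TGF-beta and stem cell factor lists (adjusted p = 0.548, 0.264 and 0.297), while fry called the TGF-beta list up (adjusted p = 0.0103). TCF7 lost its call without any 1 library except SP replicate 4 (adjusted p up to 0.104), and the losses of BMI1 are given above.

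Cell cycle genes gave a mixed picture. The topoisomerase gene TOP2A did not pass, with 26.2 ± 19.2 CPM in SP and 11.4 ± 4.07 CPM in NSP (limma-voom adjusted p = 0.242), and passed without SP replicate 4 (adjusted p = 0.0239) and with quality weights (0.0220). Of 23 mitotic genes 7 rose and 1 fell, the same over the list alone. T and NK and endothelial markers rose in the same libraries (list medians 9.96 and 8.70), and which cells held the mitotic RNA was not tested. The centromere and kinetochore genes CENPA (1.86) and NDC80 (4.18, or 1.58 with limma-trend) and the spindle gene TPX2 (1.83) rose, and CDC20 fell (-2.34). The mitotic list was called by camera at adjusted p = 0.046, with adjusted p = 0.462 with an estimated correlation. Its call ended without SP replicate 1, 2 or 3 or NSP replicate 1 or 2, with adjusted p up to 0.0886, and also with a filter of 10 reads in 4 libraries (0.0670), after thinning (0.0838) and with quality weights (0.0502). Of 14 replication genes 1 rose, CCNE2 (2.43), and 2 fell, POLA1 (-0.99) and CDC6 (-0.87), but none passed over the list alone, and the list was not called (adjusted p = 0.406). Its median was -0.19 and its mean 0.0040, and with upper-quartile factors 0 genes rose and 3 fell. Of 18 quiescence genes 6 rose and 3 fell (8 and 3 over the list alone; camera adjusted p = 0.297, fry up with adjusted p = 0.0236). The cyclin-dependent kinase inhibitor gene CDKN2C (2.06), TXNIP and BTG3 (1.18) rose, and CDKN1A (-1.08 ± 0.29, adjusted p = 0.0182), BTG2 (-1.72) and EGR1 (-1.60) fell. Several of these calls ended without single libraries: CDKN1A without NSP replicate 2 (adjusted p = 0.0539), TPX2 without NSP replicate 1 or 2 (up to 0.0705), NDC80 without NSP replicate 1, 2 or 3 (up to 0.0738), POLA1 without SP replicate 2 or 3 or NSP replicate 2 or 3 (up to 0.0731), BTG3 without SP replicate 2 or 3 or any NSP replicate (up to 0.0919), CCNE2 without any library except SP replicate 4 or NSP replicate 3 (up to 0.114) and CDC6 without any library except SP replicate 1 or 4 (up to 0.132). CCNE2 also lost its call with upper-quartile factors (adjusted p = 0.0518), and CDC6 without the filter (0.0617), with limma-trend (0.0536), with quality weights (0.0589) and after thinning (0.0526).

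Stress and immediate early genes moved both ways. Of 20 immediate early genes 3 fell, FOSL1 (-3.50), BTG2 and EGR1, and 1 rose, NR4A3 (1.99), also over the list alone (camera adjusted p = 0.158). Of 14 heat shock and unfolded protein genes 3 rose, the endoplasmic reticulum chaperones HSP90B1 (1.30) and PDIA4 (0.91) and the stress gene TRIB3 (1.78), and 2 fell, CRYAB (-1.55) and HSPA8 (-0.89), which lost its call with limma-trend (adjusted p = 0.118). With median-ratio or upper-quartile factors 1 gene of the list rose and 2 fell. Over that list alone 4 rose and 2 fell, and it was not called (camera on limma-voom values, adjusted p = 0.297), while fry called it up (adjusted p = 0.0103). Without SP replicate 4 the immediate early list was called lower (adjusted p = 0.0262) and PDIA4 moved to 0.54 and lost its call (adjusted p = 0.0541), which it also did without NSP replicate 1, 2 or 3 (up to 0.0992) and under both other scalings. NR4A3 lost its call without NSP replicate 2, 3 or 4 (adjusted p up to 0.0636) and TRIB3 without any library except SP replicate 2 (up to 0.105), with both other scalings (up to 0.0651) and without the filter (0.0502).

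Some glycolytic and antioxidant genes fell in SP cells, while 8 of 16 and 9 of 17 measured ones did not pass. ENO1 was at 1282 ± 327 CPM in SP and 10579 ± 2799 CPM in NSP (limma-voom adjusted p = 0.000141), and LDHB (-3.20 ± 0.45) and the glucose transporter SLC2A1 (-2.40 ± 0.34) fell alongside it, while the transporter SLC2A3 rose (2.44 ± 0.40). Of 16 glycolytic genes 7 fell and 1 rose (8 and 1 over the list alone). Of 20 hypoxia genes 8 fell, including P4HA2 (-1.96) and VEGFA (-2.40), and 2 rose, HIF1A (1.83) and DDIT4 (1.30), with 9 and 2 over the list alone. Of 17 antioxidant and xenobiotic genes 7 fell, including thioredoxin (TXN, -2.30), SOD1 (-1.42) and PRDX1 (-1.02), and 1 rose, the heme oxygenase gene HMOX1 (1.41), the same over the list alone. Camera called these 3 lists lower, at adjusted p = 0.00641 for glycolysis, 0.00135 for hypoxia and 0.00695 for antioxidant genes, and the calls were lost at adjusted p = 0.34, 0.336 and 0.336 with an estimated correlation. In the same libraries the corneal list had a median log2 fold change of -2.49, and the T and NK, endothelial and melanocyte lists had medians of 9.96, 8.70 and 5.13. DDIT4 lost its call without NSP replicate 1 or 3 (adjusted p up to 0.0602) and HMOX1 without SP replicate 4 or NSP replicate 1 (up to 0.0793).

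Few ribosomal protein and oxidative phosphorylation genes passed. Of 44 ribosomal protein genes 1 passed, RPS29 (2.38), also over the list alone, and the list median of 0.42 was called higher by camera (adjusted p = 0.0377), with adjusted p = 0.712 with an estimated correlation. That call also ended with median-ratio factors (adjusted p = 0.0673), with upper-quartile factors (adjusted p = 0.102) and without SP replicate 3 or 4 or NSP replicate 2 or 3 (adjusted p up to 0.318), with limma-trend (0.0926), with quality weights (0.234) and in fry (0.211). Ribosomal protein genes have many near-identical copies in mammalian genomes, which can make their read counts uncertain, and this was not measured here. Of 24 oxidative phosphorylation genes 1 rose, ATP5F1 (0.60), and 2 fell, NDUFB3 (-1.15) and NDUFB9 (-0.67), with 0 and 1 over the list alone, 0 rose and 3 fell with either other scaling, and the list was called lower with upper-quartile factors (adjusted p = 0.0461, against 0.126 with TMM factors). Of 12 cholesterol synthesis genes 3 rose, SC5D (1.36) and INSIG1 (0.86) among them, and 1 fell, PMVK (-0.93), with 3 and 2 over the list alone. The list median of 0.14 turned to -0.044 with upper-quartile factors, where 0 genes rose and 3 fell, and the list was not called (camera on limma-voom values, adjusted p = 0.837). The calls of ATP5F1 and NDUFB9 and of SC5D, INSIG1 and PMVK ended without at least 3 of the single libraries each, with adjusted p up to 0.13. ATP5F1 and INSIG1 also lost their calls under both other scalings (up to 0.149 and 0.0875) and without the filter (0.0643 and 0.0528), and SC5D with upper-quartile factors (0.0599).

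In all, 3075 of 10012 tested genes passed an adjusted p of 0.05 in limma-voom, 1774 higher and 1301 lower in SP. Leaving out 1 library gave between 2266 genes (without NSP replicate 4) and 3851 genes (without SP replicate 4). Of the 3075 genes, 2353 also passed a corrected p of 0.05 in the EDGE test of the authors' deposited table, all with the same direction; that table held 2808 such genes, 2494 of them among those tested here. The balance of directions depended on the scaling, since upper-quartile factors gave 1439 higher and 1627 lower genes. Relative to trimmed-mean (TMM) factors, they moved the log2 fold changes of all genes by a median of -0.18 and median-ratio factors moved them by -0.12, so changes of that size have no settled direction.

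The libraries separated by group. Correlations of log2 CPM over the tested genes ran from 0.813 to 0.883 among SP libraries, from 0.915 to 0.955 among NSP libraries and from 0.568 to 0.690 between the groups. The first principal component held 66.4% of the variance and separated the groups. Read totals were lower in SP, at 17394500 ± 1722500 against 21455200 ± 1401600 (SD, n = 4 each; exact two-sided permutation test, p = 0.0286, the smallest that 70 splits allow). The 10 most abundant genes took 9.57 ± 0.63% of reads in SP and 12.7 ± 0.57% in NSP (same exact test, p = 0.0286). The number of genes with at least 1 read did not differ by more than the spread, at 10949.8 ± 100.4 in SP and 11063.2 ± 519.5 in NSP (exact permutation p = 0.743).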

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

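All tests of explanations in this part were chosen after the results they address had been seen; the count over other splits was computed for the planned comparison. The values below lie far from the other 3 libraries of their group by Dixon's ratio, which picks out about 1 in 20 groups by chance; here it picked out 27 of 301 groups of 4, or 8.97%. SP replicate 4 held 12 of the 27, NSP replicate 3 held 6, SP replicate 3 held 3, NSP replicates 1 and 2 held 2 each, and SP replicate 1 and NSP replicate 4 held 1 each.

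SP replicate 4 lay above the other SP libraries for KRT15 at 2038 CPM (others 45.5 to 155), LAMB3 at 50 CPM (others 5.65 to 9.31), FRZB at 20.6 CPM (others up to 2.88), GPHB5 at 25.4 CPM (others up to 0.0517) and CXCL14 at 5.58 CPM (others 0.707 to 1.02). The same library was the high one for EXTL1 at 3.84 CPM (others 0), MMP3 at 8.30 CPM (others up to 0.108), TENM2 at 6.97 CPM (others up to 0.431) and CDH10 at 2.16 CPM (others up to 0.0544). It was also high for PDIA4 at 1251 CPM (others 612 to 692), LEF1 at 125.4 CPM (others 45.3 to 58.4) and VEGFA at 44.5 CPM (others 15.3 to 19.2). KRT12 was highest in SP replicate 1 at 3833 CPM (others 169.1 to 645). SP replicate 3 was high for CORO1A at 423.6 CPM (others 243.6 to 264.7), WAS at 107.8 CPM (others 62.2 to 69.6) and ATP5F1 at 355.5 CPM (others 289.8 to 296.6).

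In NSP replicate 3, ABCC1 was low at 35.0 CPM (others 96.6 to 103.9) and CRYAB at 460.5 CPM (others 712.5 to 751.1), while FOSL1 at 488.7 CPM (others 381.9 to 384.4), IFIT2 at 19.1 CPM (others 4.23 to 5.27), HSPG2 at 45.3 CPM (others 24.6 to 28.0) and CD34 at 0.599 CPM (others 0) were high. In NSP replicate 1 the 10 most abundant genes held 13.6% of reads (others 12.4 to 12.5%), and CLDN1 was at 432.7 CPM (others 229.3 to 261.2). NSP replicate 2 was high for VWF at 1.06 CPM (others up to 0.135) and low for SELP at 0.0462 CPM (others 0.135 to 0.150), and NSP replicate 4 was high for CD247 at 0.387 CPM (others up to 0.0499); these 3 genes are near the limit of detection in NSP.

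The count of 3075 genes between SP and NSP was set against all other splits of the 8 libraries into 4 and 4. Of 35 splits, 1 gave as many genes, the real one, and the highest of the others gave 0. A share of 1 in 35 is the smallest these splits allow. Every other split also mixes SP and NSP libraries, which widens the spread within its groups, so the count cannot exclude chance.

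Markers of stromal, pigment, vessel and immune cells were higher in SP: of 76 measured markers, 64 rose and 1 fell. After thinning to equal totals 100% of the 64 raised markers passed again, so their calls did not rest on unequal totals. This outcome was likely in advance, since SP libraries held fewer reads than NSP libraries and the markers were picked as called in the same data. The mean differences were 4.80 for stromal, 5.79 for melanocyte, 8.44 for T and NK and 7.99 for endothelial genes on the log2 scale. Their range was 3.64 (exact permutation p = 0.0286). The NSP means also differed, at 0.18, 1.43, -2.96 and -2.13 log2 CPM in the same order. A list's background in NSP affects the size of its difference. The range therefore cannot decide whether a lower share of epithelium lifted every other cell type alike. RNA from such cells in the SP gate stays open: 84.2% of the markers rose against 17.7% of all tested genes, which restates the pattern and cannot decide for this source or another. The share is also raised by the filter, which markers nearly absent from NSP could pass only through SP. Levels in SP were unlike between the types. CCL5, SELP, VWF and PMEL averaged 3383, 3151, 3239 and 1845 CPM, and the stromal genes COL1A1 and COL1A2 only 71.9 and 61.9 CPM. Another list also holds 3 of the stromal genes and 1 gene each of the melanocyte, myeloid and pan-leukocyte lists. The labels name a sort on the dye and do not say whether cells were also gated on CD45 or CD31. Expression of these genes by the limbal epithelium itself was not tested.

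Genes of the corneal list were lower in SP, and those of the conjunctival list were not called as a group. Dilution of 1 epithelium by RNA of cells that make genes of neither list would lower both alike, and only this narrow form is argued against. The corneal minus conjunctival list mean was -0.921 ± 0.817 in SP and 1.03 ± 0.443 in NSP, a difference of -1.95 on the log2 scale (exact permutation p = 0.029, the smallest possible). Dilution by cells that make conjunctival genes cannot be decided by this contrast, since it would lower the lists unequally. Simple keratins from other cells are argued against as the whole reason, since without KRT7, KRT8 and KRT18 the difference was -1.63 (exact p = 0.029). The corneal mean differed by -2.33 (exact p = 0.029) and the conjunctival one by -0.379 (exact p = 0.66), the latter with 7.58 ± 1.3 in SP and 7.95 ± 0.367 in NSP. Of the 10 measured conjunctival genes, 2 fell (KRT13 and KRT4), 1 rose and 7 did not pass. Other conjunctival genes made by non-epithelial cells, and a different mix of epithelial cells in the gate, stay open.

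The stratified keratins differed between SP and NSP by unequal amounts, from -6.41 for KRT15 to -1.47 for KRT4 among those that fell. Equal dilution of all epithelial RNA, which would lower them alike, is argued against: the differences of the 8 measured stratified keratins had a range of 7.24 on the log2 scale, and the 6 called ones alone a range of 4.92 (exact permutation p = 0.0286 for each, the smallest possible). For the pair KRT12 and KRT3 against KRT15 and TP63 alone, the log2 ratio was 3.20 ± 1.61 in SP and 0.691 ± 0.987 in NSP, a difference of 2.50 that did not pass (exact permutation p = 0.0571). A different mix of epithelial cells in the gate, and keratin RNA from other cells, stay open.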

How the results depend on the processing

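The alternatives limma-trend, quality weights and thinning were chosen after seeing the data; the others were planned before the data were examined. The number of genes past the threshold was 3075, and 3053 with median-ratio factors, 3066 with upper-quartile factors, 3185 without the filter, 3070 with the stricter one, 3218 with limma-trend, 3940 with quality weights and 3000 after thinning. Leaving out 1 library gave 2266 (without NSP replicate 4) to 3851 (without SP replicate 4), and under each of these settings every gene called in both fits kept its direction. Genes higher in SP made up 57.7% of calls, 51.0% with median-ratio factors, 46.9% with upper-quartile factors and 49.0% without NSP replicate 1. Camera called 19 lists, 17 to 19 without 1 library, 17 to 21 under the other scalings, filters and added alternatives, 0 with an estimated correlation and 25 with fry. The first principal component held 66.4% of the variance over all tested genes and 87.7% over the 500 most variable ones; the reason was not tested. Over the named genes, 2063 values kept direction and side of the threshold, 138 lost their call and 2 gained one; none reversed. Over the lists, 508 values stayed on their side of the threshold, 37 lost their call, 15 gained one and 1 reversed: the ABC transporter list, which camera leaned down (not called), was called up by fry (adjusted p = 0.0322), and the cause was not tested. Of 147 named genes tested, 118 passed in every fit that left out 1 library. On the log2 scale 9 called named genes moved by more than 1.5 times with limma-trend, whose added count shrinks genes of few reads, such as CD8B to 5.90, SAMSN1 to 7.95, COL3A1 to 4.22 and TSPYL5 to -3.70, and 1 did with quality weights, TJP1 to 0.62. No paired analysis was possible because the columns carry no replicate number. Not run were the Wald test of DESeq2, limma on RPKM values, pseudocounts and quantile scaling for normalized values, a replicate block, and leaving out both libraries of a number. At these totals and this spread between libraries, which the simulation did not separate, it recovered 7.29% of 2-fold and 68% of 8-fold changes. It changed only 200 genes, while 30.7% of tested genes were called in the real comparison. Fewer changed genes make the adjusted threshold stricter, so these rates may be too low.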

Other observations

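The tests in this part were chosen after the values were seen. Endothelial genes had their highest mean log2 CPM in SP replicate 4 (7.45, others 3.59 to 6.22), T and NK genes in SP replicate 3 (6.57, others 4.67 to 5.91), melanocyte genes in SP replicate 1 (8.46, others 5.97 to 7.90) and stromal genes in SP replicate 3 (5.51, others 4.40 to 5.30). Among NSP libraries, melanocyte genes stood at 3.10 in replicate 4 and 0.256 to 1.41 in the others.

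Melanocyte genes were abundant in SP: PMEL, which encodes the fibrils on which pigment is laid down, was at 1845 ± 1242 CPM in SP and 51.4 ± 35.2 CPM in NSP cells. The table also holds 72 called genes with no NSP read and 10 called genes with no SP read. After thinning to equal read totals, SP libraries had 219.25 more genes with at least 5 reads than NSP libraries (exact permutation p = 0.0571) and a difference of -24.25 for at least 1 read (p = 0.943).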
